A study of Homo sapiens with 9 samples.

How the data were processed

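Expression was measured by RNA sequencing of GBM43 cells in hyaluronic acid gel devices. Per the labels' protocols, control devices were cut with a scalpel into core and invasive fractions, MK801 devices (50 µM) were taken whole, the gel was digested with hyaluronidase, RNA was extracted with Trizol, and libraries were made from poly-A selected RNA by a sequencing provider. The labels give both culture medium and DMSO as what control devices received. There were 3 core, 3 invasive and 3 MK801 libraries, each mapped to its column of the deposited table by the column name in its label, and 0 value columns were left unmapped.

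The deposited values are FPKM per gene, 58735 genes in all, with the gene length the authors used beside them. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCh38, without their settings, so it is not known whether strand was used. Overlapping and antisense genes and near-identical paralogs such as HSPA1A and its neighbour HSPA1B are therefore uncertain. All gene identifiers and coordinates matched GENCODE release 29 (100%). FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values above 0 (tolerance 0.01 fragments), so fragments could be recovered. The recovered totals were 15.6 to 54.4 M fragments. The library total by which the authors divided was 0.769 to 1.23 times the recovered gene total, for a reason not given in the sources used here. This ratio was 1.10 to 1.23 in core, 0.788 to 1.06 in invasive and 0.769, 0.937 and 1.19 in MK801 libraries. The scaling of FPKM relative to the gene total therefore differed between core and invasive libraries. The precision of a low value follows from these depths, and 0 fragments was given an upper limit of 3 fragments, which covers counting error only.

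FPKM was analysed as log2(FPKM + 1). A gene was tested if it reached 1 FPKM in at least 3 libraries, which left 11845 genes. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 9 libraries, with empirical Bayes and a mean-variance trend (6 residual degrees of freedom), and p was adjusted by Benjamini-Hochberg over genes with a threshold of 0.05. The contrasts were invasive minus core, MK801 minus core, MK801 minus invasive, and MK801 minus the equal-weight mean of the control fractions. An exact permutation test of 3 against 3 libraries cannot give p below 0.1, so no single-gene permutation p is given. Lists of genes were fixed before the data were examined, 47 lists with 1300 symbols of which 1298 matched a gene, and the 39 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move on balance, and does not compare them with other genes. The correlation of contrasts was set beside 100 simulated draws of unchanged groups made from the libraries' own deviations. The planned fry test of genes called in invasive versus core could not be made in the 9-library fit, which called none, so the genes called in the GC-corrected fit of the 6 control libraries were used, a choice made after the data were seen.

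The rule for named genes was fixed before the data were examined. Per contrast it takes the 6 highest and 6 lowest protein-coding genes with a mean of at least 5 FPKM, groups that do not overlap and an adjusted p past the threshold, or, as happened here, those with the smallest p where too few pass. It adds up to 4 members with the smallest p from each list that passes or belongs to a set of named themes, and the NMDA receptor subunits. Which of those list members the text names, and DCN and LUM, were chosen after their values were seen. Y-linked genes and XIST were left out, and some genes that the rule takes are not reported here.

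Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a fixed block or random effect, the groups compared alone, robust empirical Bayes, library quality weights, a fold change above 1.2, protein-coding genes only, voom on recovered fragments, and leaving out each library of the groups compared. Chosen after the data were seen were the removal of each library's loess trend (span 0.3) over gene GC content, with or without length, the number of genes detected as a covariate, leaving out the 2 libraries with the fewest genes detected, leaving out libraries outside a comparison, and combinations of these. For the lists, leaving out each library and the groups compared alone were also chosen after the data were seen. GC content was taken from GENCODE transcripts and was known for 99.97% of tested genes. The number of genes detected was computed at 15.6 M fragments.

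The gene-wise procedure was tested on simulated data for invasive versus core over 11845 genes, with 100 genes changed by log2 1 and 100 by log2 2. With independent spread of smaller size than observed, 85% and 99% were recovered, with 9 false calls. With the observed deviations of the libraries shuffled and given random signs, 14% and 93% were recovered with 0 false calls, and after GC correction 55% and 99%. This was a single draw. Deviations shared by many genes make false calls vary between draws, so it does not show that they are controlled. With a GC trend per library, 67% and 96% were recovered with 35 false calls, and after correction 82% and 99% with 19, so GC correction did not remove all false calls. Of simulated lists, the 1 moved list was called and 0 of 100 unmoved lists were. These lists were drawn with spread independent between genes. In the real libraries a single axis held 66.9% of the variance within groups. The simulation therefore cannot show how often camera calls unmoved lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.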

Results

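RNA sequencing was used to measure gene expression in GBM43, a glioblastoma line derived from a patient tumour, grown in hyaluronic acid gel devices that let cells invade the gel around a central core. Control devices were cut into a core fraction and an invasive fraction, and devices treated with 50 µM MK801, a blocker of the NMDA class of glutamate receptors, were sequenced as pooled core and invasive cells because few cells had invaded. The series asks what extracellular glutamate and NMDA receptors contribute to invasion. There were 9 libraries, 3 in each of 3 groups. The deposited FPKM values corresponded to 15.6 to 54.4 M fragments (M for 1e6) assigned to genes per library. Core libraries held 23.7, 15.6 and 18.3 M, invasive libraries 16.7, 22.8 and 18.7 M, and MK801 libraries 18.4, 16.5 and 54.4 M. Nothing in the sample descriptions says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Unless stated otherwise, levels are mean FPKM ± SD of n = 3 libraries per group, coordinates are on GRCh38, and fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes.

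The libraries differed in how many genes they detected and in the GC content of their transcripts. At an equal depth of 15.6 M fragments, 20322 to 21414 genes were detected in core libraries and 15975 to 19140 in invasive libraries. The MK801 libraries spanned the whole range, with 15161, 19031 and 21517 genes. The mean GC content of transcripts, weighted by fragments, was 49.8 to 51.1% in core, 52.7 to 54.4% in invasive and 54.2, 53.1 and 50.5% in the MK801 libraries. Pairwise correlations across genes were 0.968 to 0.976 within the core group and 0.959 to 0.980 within the invasive group, but 0.839 to 0.947 within the MK801 group. MK801 replicate 1 correlated best with invasive replicate 2, MK801 replicate 2 with invasive replicate 1, and MK801 replicate 3 with core replicate 2.

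**Figure D1:**
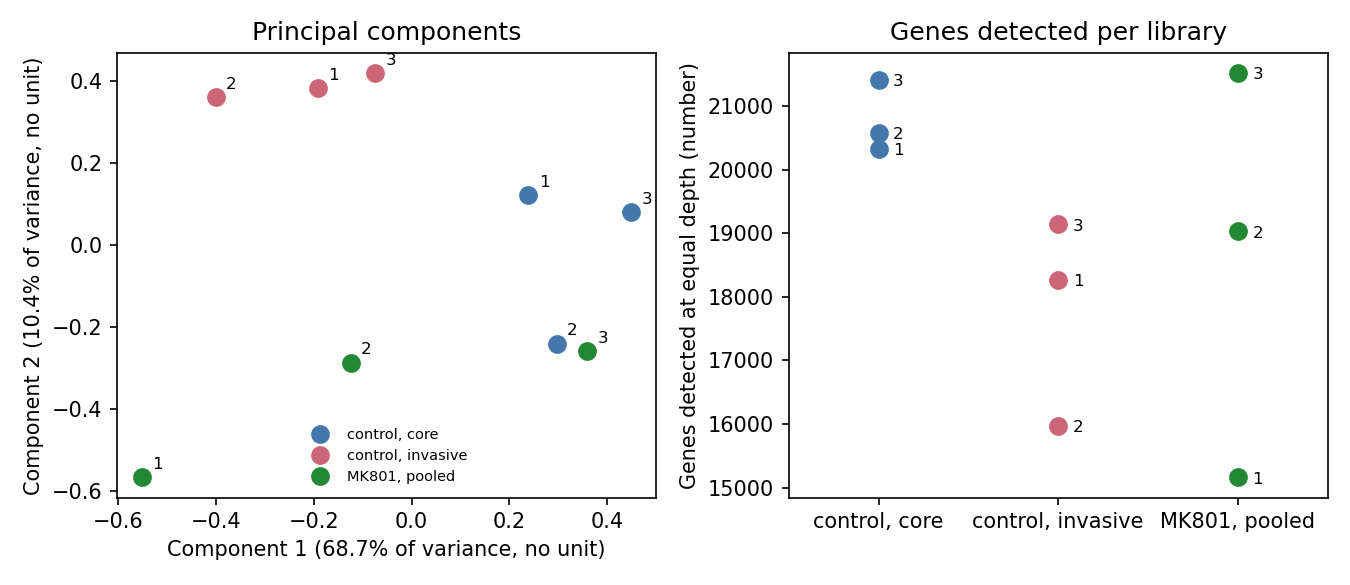
Left, first and second principal components (no unit, 68.7% and 10.4% of variance) of log2(FPKM + 1) over 11845 genes. Right, number of genes detected at 15.6 M fragments. Each point is 1 library, coloured by group and marked with its replicate number. The 3 MK801 libraries spread along the first component from the invasive to the core side, and every invasive library detected fewer genes than every core library.

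Transcripts of NMDA receptor subunits were scarce in all groups. GRIN1 (ENSG00000176884, chromosome 9, 137138390 to 137168762), which encodes the subunit that NMDA receptors require, had 0 fragments in all 9 libraries, which allows a level of up to 0.0315 FPKM in the library where the limit is highest, for counting error alone. Of 7 NMDA subunit genes, 6 stayed under 1 FPKM in every library. The exception was GRIN2D (ENSG00000105464, chromosome 19, 48394875 to 48444931), which encodes a regulatory subunit, at 0.273 ± 0.0536 FPKM in core, 1.26 ± 0.967 in invasive and 0.875 ± 0.463 in MK801 libraries. GRIN2D did not differ past the threshold in any comparison (limma adjusted p = 0.128 for invasive versus core), and the sign of that difference turned when the GC trend was removed (log2 0.74 before, -0.13 after). All 19 AMPA, kainate, delta and metabotropic glutamate receptor genes were under 1 FPKM in every library.

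The first comparison asked how invasive cells differ from core cells of control devices. Genes that build the extracellular matrix were higher in the invasive fraction. COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632), a chain of type I collagen, was at 247 ± 82.2 FPKM in invasive and 37.4 ± 17.7 in core libraries, a 6.67-fold difference (log2 2.74, SE 0.48). COL1A2, its partner chain, was at 163 ± 39.6 against 47.2 ± 19.3 FPKM. FN1, which encodes fibronectin, was at 100.6 ± 40.9 against 26.9 ± 11.9 FPKM. Of 35 matrix genes tested, 31 were higher and 4 lower, with a median log2 difference of 1.07, and the list rose (camera adjusted p = 1.0e-08, but adjusted p = 0.534 with an estimated correlation). Adjusted over the list alone, 23 matrix genes were past the threshold, all higher, and over all genes tested 0 were. Markers of fibroblasts and pericytes rose as well (8 of 10 higher, median 1.19, camera adjusted p = 0.0021, adjusted p = 0.534 with an estimated correlation), a list that holds the matrix genes COL1A1, COL1A2 and COL3A1 and also PDGFRB, a growth factor receptor, at 48.1 ± 15.5 against 11.6 ± 2.97 FPKM.

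The genes named first for this comparison by the fixed rule were not past the threshold in the fit of all 9 libraries. The 6 higher ones were CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373) and CCN1, both secreted matrix-associated proteins, CSF1, a macrophage growth factor, FAM20C, a kinase of secreted proteins, UNC5B, a netrin receptor, and SCARF2, a scavenger receptor. CCN2 was at 45.7 ± 10.8 FPKM in invasive and 11 ± 2.9 in core libraries (log2 1.97, SE 0.28, limma adjusted p = 0.059). CSF1 was at 35.1 ± 2.2 against 6.75 ± 2.13 FPKM, and CCN1 at 135 ± 31.5 against 42.3 ± 3.9 FPKM. The 6 lower ones were HAS2, ADPRM, TFPI2, PPIL3, the heat shock gene HSPA1A and EVI2A. HAS2 (ENSG00000170961, chromosome 8, 121612116 to 121641390), which encodes a synthase of hyaluronan, the polymer of the gel, was at 4.57 ± 0.941 FPKM in invasive and 14.8 ± 2.16 in core libraries (log2 -1.51, SE 0.28, limma adjusted p = 0.075). CEMIP, which takes part in hyaluronan breakdown, was at 3.96 ± 1.34 against 0.268 ± 0.0903 FPKM. MMP1, an interstitial collagenase, was at 30.4 ± 6.43 against 78.9 ± 14.7 FPKM, and TFPI2, a serine protease inhibitor, at 5.04 ± 1.7 against 15.4 ± 3.04 FPKM. TIMP3 and TIMP2, inhibitors of matrix metalloproteinases, were higher in invasive libraries, at 44.2 ± 2.28 against 14.5 ± 5.75 and 136 ± 19.4 against 43.3 ± 13 FPKM. As lists, matrix proteases and inhibitors (19 of 31 higher, camera adjusted p = 0.303) and hyaluronan genes (6 of 11 higher, camera adjusted p = 0.318) did not pass. Fry, which does not compare a list with other genes, called the hyaluronan list higher (fry adjusted p = 0.0052, and 0.010 after GC correction).

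**Figure D2:**
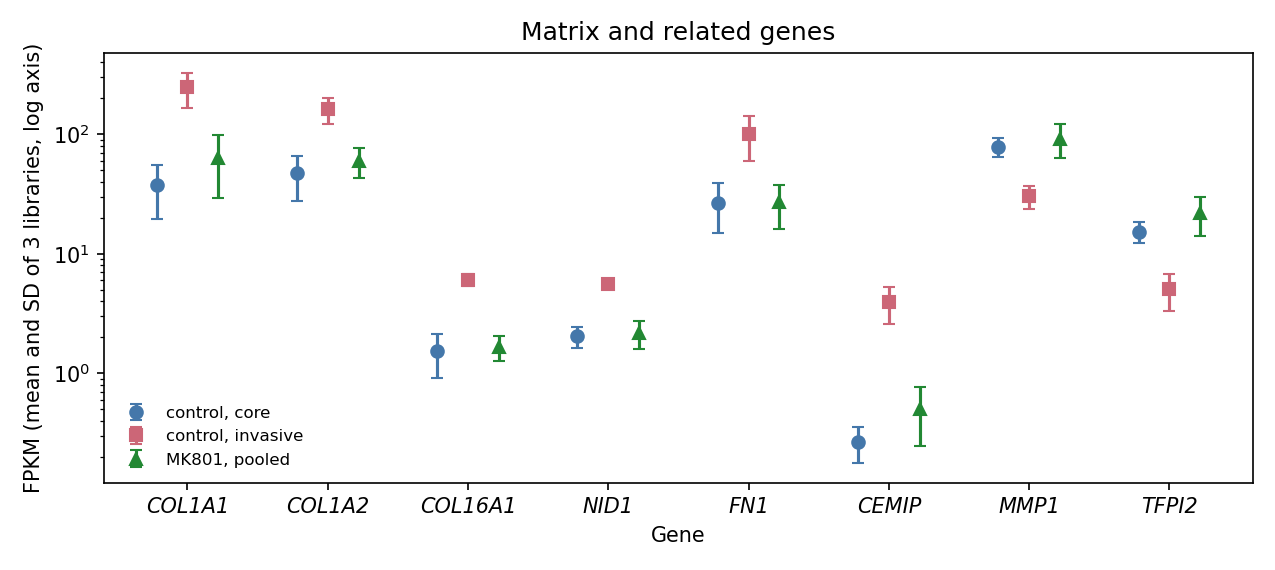
Mean FPKM (log axis) of 8 matrix and related genes in core, invasive and MK801 libraries. Symbols are means and bars are the SD of 3 libraries. COL1A1, COL1A2, COL16A1, NID1, FN1 and CEMIP were highest in the invasive fraction, where MMP1 and TFPI2 were lowest.

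Genes of DNA replication rose in the invasive fraction (34 of 40 higher, median 0.63, camera adjusted p = 6.2e-05, adjusted p = 0.534 with an estimated correlation), with 18 of them past the threshold adjusted over the list alone and 0 over all genes tested. MCM2 and MCM5, parts of the replicative helicase, were at 40.1 ± 8.17 against 9.81 ± 3.01 and 23.6 ± 4.25 against 5.62 ± 1.09 FPKM. Mitosis genes as a list did not pass (22 of 43 higher, median 0.09, camera adjusted p = 0.193), although FOXM1, a transcription factor of the cell cycle, was at 19.3 ± 1.11 against 5.36 ± 1.78 FPKM. With the GC trend removed, the mitosis list passed with a median of 0.58 (adjusted p = 0.513 with an estimated correlation). Genes of cholesterol biosynthesis and uptake, a list that also holds fatty acid enzymes, rose (22 of 33 higher, median 0.70, camera adjusted p = 0.0039, adjusted p = 0.534 with an estimated correlation). Among them FADS2, a fatty acid desaturase, was at 126 ± 26.3 against 34.5 ± 12.1 FPKM. Hypoxia response genes fell (23 of 34 lower, median -0.35, camera adjusted p = 0.032, adjusted p = 0.534 with an estimated correlation). MXI1 and BNIP3L, both induced by hypoxia, were at 10.6 ± 1.02 against 26.1 ± 5.04 and 37.3 ± 6.28 against 91.6 ± 9.05 FPKM. The hypoxia call was lost without core replicate 1 (median -0.22, adjusted p = 0.086) or invasive replicate 3 (adjusted p = 0.10). Activity-regulated immediate-early genes, which many stimuli induce within minutes, rose before the GC trend was removed (23 of 28 higher, median 0.55, camera adjusted p = 0.0039, adjusted p = 0.534 with an estimated correlation) and not after (median -0.03, adjusted p = 0.98). JUNB, one of them, was at 389 ± 38.4 against 184 ± 25.2 FPKM. In all, 12 lists rose and 1 fell of 39 tested. The 7 not yet described that rose were nuclear-encoded oxidative phosphorylation, glycolysis, lysosome and autophagy, the mesenchymal-like glioblastoma state, axon guidance, integrins and focal adhesion, and NF-kB and inflammatory cytokines. Their adjusted p was 0.534 to 0.573 with an estimated correlation, with which 0 of the 39 lists passed. The call of axon guidance was lost without MK801 replicate 1, those of glycolysis and the mesenchymal-like state without invasive replicate 2 (medians 0.37 and 0.41), that of integrins without any 1 of invasive replicate 2 and MK801 replicates 1 and 3, and that of NF-kB in 6 of 9 such fits. Without MK801 replicate 1 and invasive replicate 2 together, the calls of integrins (camera adjusted p = 0.177), glycolysis (0.068) and axon guidance (0.066) were lost. Removing the GC trend ended the calls of integrins (median 0.61 before and 0.15 after, adjusted p = 0.064) and NF-kB (0.45 and 0.12, adjusted p = 0.339). With the number of genes detected as a covariate, those of oxidative phosphorylation (median 0.53 before and 0.07 after, adjusted p = 0.893), glycolysis (0.70 and 0.04, adjusted p = 0.893) and the mesenchymal-like state (0.63 and 0.06, adjusted p = 0.377) were lost. By fry, 7 of the 13 lists passed, and those not past were DNA replication and lysosome (adjusted p = 0.056 for each), integrins (0.060), the mesenchymal-like state (0.099), glycolysis (0.213) and oxidative phosphorylation (0.216). Adjusted over the list alone, 15 cholesterol genes were higher and 1 lower, 1 immediate-early gene was higher and 0 hypoxia genes passed.

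Limma on all 9 libraries called 0 of 11845 genes in invasive versus core, with a smallest adjusted p of 0.059 and 4461 genes at an unadjusted p under 0.05, and limma-voom on recovered fragments also called 0. Fitted on the 6 control libraries alone, an alternative set before the data were examined that leaves the wider spread of the MK801 libraries out, limma called 6179 genes, 3117 higher and 3062 lower, among them all 12 genes named first. With the GC trend removed, that fit called 2037 genes, 1068 higher and 969 lower, of which 1386 were shared with the uncorrected calls, all with the same sign. Leaving out MK801 replicate 1 or replicate 3 from the 9-library fit gave 4675 and 4888 genes. The labels do not say whether fractions of the same number came from 1 device, although their column names share a stem. With the replicate number as a block, 2525 genes were called, and the hypoxia and NF-kB lists were not (adjusted p = 0.054 for each). This block also joins the MK801 libraries of the same number, so it does not isolate a pairing of core and invasive fractions. After GC correction, limma with the block called 0 genes, with 2861 at an unadjusted p under 0.05. The 3 libraries of each fraction did not overlap for 64.8% of genes. Chance gives 10% on average over splits, but genes that move together can lift a single split far above it, so this share does not measure evidence against chance. The difference per gene followed GC content across genes (Spearman's rho 0.774, genes not being independent replicates). It followed the main axis of variation within groups more closely (Spearman's rho 0.869). That axis held 66.9% of the variance within groups and mainly parted MK801 replicate 1 from replicate 3 (loadings 0.650 and -0.646). The difference between the fractions thus lay largely along variation also seen between replicates of 1 group.

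**Figure D3:**
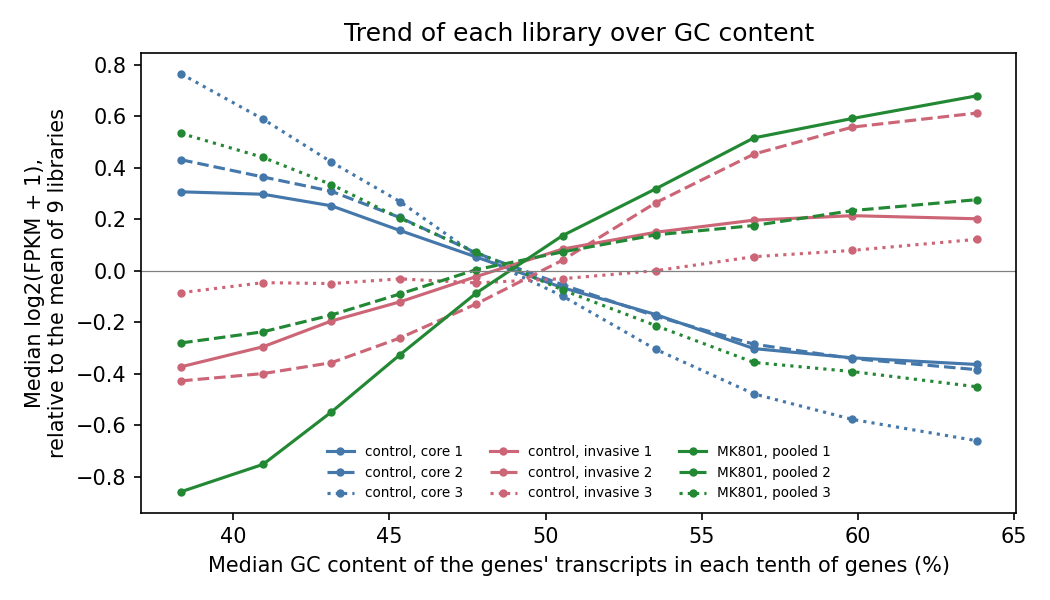
Median log2(FPKM + 1) relative to the mean of the 9 libraries, for 10 equal bins of the tested genes ordered by the GC content of their transcripts (percent). Each line is 1 library, coloured by group, with solid, dashed and dotted lines for replicates 1, 2 and 3. Core libraries and MK801 replicate 3 fall with GC content, and the invasive libraries and MK801 replicates 1 and 2 rise.

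The comparison of MK801 with the core fraction asked how the treated cells differ from control cells that had not invaded. Hypoxia and mitosis genes were lower in MK801 libraries. Of 34 hypoxia response genes 26 were lower (median -0.41, camera adjusted p = 0.021, adjusted p = 0.467 with an estimated correlation), so the list fell, with 1 member past the threshold adjusted over the list alone. Of 43 mitosis genes 32 were lower (median -0.53, camera adjusted p = 0.00084, adjusted p = 0.759 with an estimated correlation), and this list fell too, with 0 members past the threshold adjusted over the list alone. P4HA1, a collagen prolyl hydroxylase, was at 18.8 ± 9.94 FPKM in MK801 and 43.0 ± 2.06 in core libraries, and CA12, a carbonic anhydrase, at 65.9 ± 6.14 against 120 ± 18.9 FPKM. CDK1, the main mitotic kinase, was at 3.10 ± 2.29 against 9.19 ± 2.46 FPKM, and KIF11, a spindle motor, at 1.84 ± 1.1 against 5.32 ± 1.91 FPKM. With the GC trend removed the hypoxia list stayed past the threshold (median -0.17, adjusted p = 0.121 with an estimated correlation) and the mitosis list did not (median -0.10, adjusted p = 0.181). Fry called the hypoxia list but not the mitosis list (adjusted p = 0.175). The hypoxia call was lost without core replicate 1 (adjusted p = 0.058) or MK801 replicate 3 (adjusted p = 0.077). Matrix genes did not differ as a list (20 of 35 higher, camera adjusted p = 0.569), and their median of 0.04, mean of -0.05 and test differed in sign. With the GC trend removed that list passed with a median of -0.28 (adjusted p = 0.890 with an estimated correlation).

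No single gene passed in MK801 versus core. The 6 named as higher were SLC12A8, RBM38, ZC3H12A, G0S2, PIM2 and TIMP3, and the 6 named as lower HAS2, TMEM200A, CRYZ, HSPA1A, LOX and PPIL3. SLC12A8 (ENSG00000221955, chromosome 3, 125082636 to 125212864), a solute carrier, was at 9.23 ± 1.52 FPKM in MK801 and 3.52 ± 0.54 in core libraries (log2 1.17, SE 0.21, limma adjusted p = 0.235). ZC3H12A, an RNase that limits cytokine mRNAs, was at 19.7 ± 3.43 against 8.92 ± 0.519 FPKM. HAS2 was at 4.70 ± 2.19 against 14.8 ± 2.16 FPKM (log2 -1.53, SE 0.28, limma adjusted p = 0.235), close to its level of 4.57 ± 0.941 FPKM in invasive libraries. LOX, which encodes lysyl oxidase, a collagen crosslinking enzyme, was at 14.6 ± 5.4 against 35.9 ± 5.59 FPKM. Limma called 0 genes, with 2509 at an unadjusted p under 0.05, and limma-voom called 0. Without MK801 replicate 3, 5941 genes were called.

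The comparison of MK801 with the invasive fraction gave the most gene lists that fell. Extracellular matrix genes fell, 33 of 35 being lower in MK801 libraries, with a median log2 difference of -1.07 (camera adjusted p = 7.1e-31, adjusted p = 0.168 with an estimated correlation). Adjusted over the list alone, 28 of them were past the threshold, all lower, and 0 over all genes tested. COL1A1 was at 63.9 ± 34.3 FPKM in MK801 and 247 ± 82.2 in invasive libraries (log2 -2.07, SE 0.48), FN1 at 27.1 ± 11 against 100.6 ± 40.9 FPKM, and COL7A1 and COL6A3 at 6.44 ± 1.09 against 19.9 ± 6.37 and 36.6 ± 13.6 against 103 ± 22.5 FPKM. TGFBI, an adhesion protein of the matrix, was at 77.9 ± 48.4 against 276 ± 121 FPKM. All 43 mitosis genes were lower (median -0.67, camera adjusted p = 5.0e-18, adjusted p = 0.168 with an estimated correlation), as were 37 of 40 DNA replication genes (median -0.68, camera adjusted p = 1.4e-16, adjusted p = 0.168 with an estimated correlation), and both lists fell. Adjusted over the list alone, 3 mitosis and 8 replication genes passed, all lower. MKI67, which encodes the proliferation marker Ki-67, was at 3.66 ± 0.22 against 7.79 ± 0.828 FPKM, and MCM10, a replication factor, at 0.792 ± 0.149 against 2.19 ± 0.167 FPKM. Fibroblast and pericyte markers moved with the matrix genes (9 of 10 lower, median -0.85, camera adjusted p = 1.8e-08, adjusted p = 0.168 with an estimated correlation).

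Of the 39 lists, 14 fell and 2 rose in MK801 versus invasive. Axon guidance genes fell (18 of 21 lower, median -0.37, adjusted p = 0.168 with an estimated correlation), among them SLIT2, a guidance ligand, at 0.790 ± 0.306 against 3.09 ± 0.593 FPKM. The astrocyte-like glioblastoma state fell (12 of 13 lower, median -0.42, adjusted p = 0.168 with an estimated correlation), as did epithelial-mesenchymal transition genes (16 of 21 lower, median -0.36, adjusted p = 0.174 with an estimated correlation). Hyaluronan genes fell (8 of 11 lower, median -0.31, adjusted p = 0.168 with an estimated correlation), with CEMIP (ENSG00000103888, chromosome 15, 80779343 to 80951776) at 0.505 ± 0.258 against 3.96 ± 1.34 FPKM (log2 -1.70, SE 0.25, limma adjusted p = 0.081). Cytoplasmic ribosomal proteins rose slightly (59 of 65 higher, median 0.22, adjusted p = 0.665 with an estimated correlation), a call lost without MK801 replicate 1 (median -0.01, adjusted p = 0.706), and p53 targets and apoptosis genes rose (18 of 28 higher, median 0.15, adjusted p = 0.168 with an estimated correlation), a call lost without MK801 replicate 1 (adjusted p = 0.371) or replicate 2, or invasive replicate 1 or 3. The other lists that fell were the oligodendrocyte-progenitor-like state, integrins and focal adhesion, immediate-early genes, cholesterol biosynthesis, the interferon response and oxidative phosphorylation, with adjusted p of 0.168 to 0.792 with an estimated correlation. Leaving out MK801 replicate 1 ended the calls of the first 3 of these, and leaving out MK801 replicate 3 those of all but the first. An invasive library also ended each of them when left out. Removing the GC trend ended the call of immediate-early genes (median -0.39 before and -0.24 after, adjusted p = 0.378), and the covariate that of oxidative phosphorylation (-0.19 and -0.05, adjusted p = 0.280). Without both MK801 replicate 1 and invasive replicate 2, the libraries with the fewest genes detected, the calls of epithelial-mesenchymal transition (median -0.15, adjusted p = 0.067), ribosomal proteins, p53 targets, hyaluronan, integrins and immediate-early genes were lost. By fry, 8 of the 16 passed, and those not past were DNA replication (adjusted p = 0.054), epithelial-mesenchymal transition (0.072), integrins, immediate-early genes, cholesterol biosynthesis, the interferon response, oxidative phosphorylation and ribosomal proteins. The hyaluronan call was lost without invasive replicate 3 or any 1 of the MK801 libraries. Single libraries also moved medians by over 1.5 times. Leaving out MK801 replicate 1 gave -0.12 for axon guidance, -0.05 for the oligodendrocyte-progenitor-like state, -0.24 for immediate-early genes, -0.34 for cholesterol, -0.36 for interferon, -0.47 for oxidative phosphorylation and 0.26 for p53 targets. Leaving out MK801 replicate 2 gave -0.15 for interferon and -0.13 for oxidative phosphorylation, and leaving out MK801 replicate 3 gave -0.17 for immediate-early genes, -0.07 for cholesterol, 0.04 for oxidative phosphorylation and 0.47 for ribosomal proteins. Leaving out invasive replicate 2 gave -0.17 for hyaluronan, -0.04 for oxidative phosphorylation and 0.34 for ribosomal proteins, and leaving out invasive replicate 3 gave -0.28 for integrins, -0.11 for interferon and 0.24 for p53 targets.

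**Figure D4:**
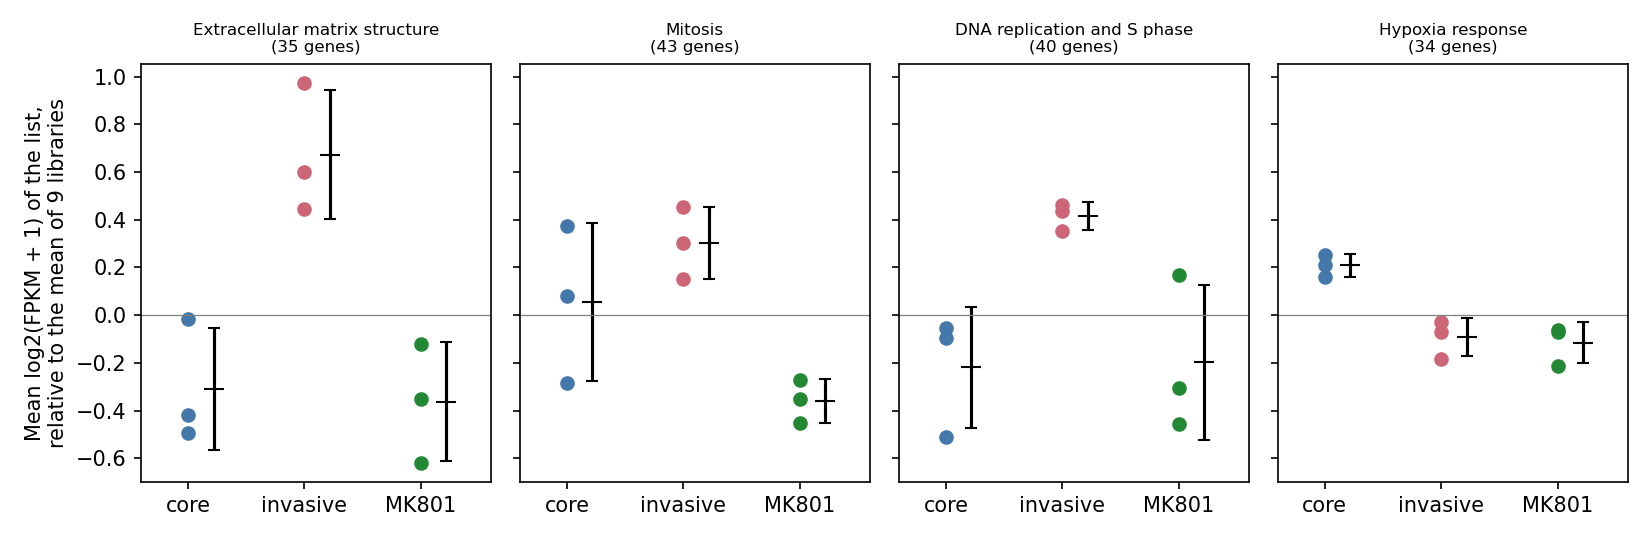
Mean log2(FPKM + 1) of 4 gene lists in each library, relative to the mean of the 9 libraries. Points are libraries and black bars are the mean and SD of 3 libraries. Matrix and DNA replication genes were highest in the invasive fraction, mitosis genes lowest in MK801 libraries and hypoxia response genes highest in the core.

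Among single genes the 6 named as higher in MK801 than in invasive libraries were TFPI2, LCP1, SLC39A11, CALB2, MMP1 and MAGEH1, and the 6 named as lower were COL7A1, RPN2, LSP1, COL6A3, ANPEP and NR2F1. TFPI2 (ENSG00000105825, chromosome 7, 93885396 to 93890991) was at 22.2 ± 8.02 FPKM in MK801 and 5.04 ± 1.7 in invasive libraries (log2 1.93, SE 0.29, limma adjusted p = 0.081). LCP1, an actin-bundling protein, was at 60.4 ± 5.92 against 24.4 ± 0.365 FPKM, CALB2, a calcium-binding protein, at 46.6 ± 10.7 against 13.1 ± 4.8 FPKM, and MMP1 at 92.4 ± 29.3 against 30.4 ± 6.43 FPKM. ANPEP, a membrane aminopeptidase, was at 10.3 ± 4.29 against 35.3 ± 10.8 FPKM. Limma called 0 genes with 978 at an unadjusted p under 0.05, and limma-voom called 0. With the GC trend removed, a step chosen after the data were seen, 74 genes passed, 44 higher and 30 lower, including TFPI2 (adjusted p = 0.021), CALB2, MMP1, CEMIP and COL1A1. Without MK801 replicate 1, 42 genes passed without that correction.

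MK801 libraries were last compared with the equal-weight mean of the control fractions. The share of core cells in the pools is unknown, so this mean need not match it. A pool of mostly core cells would lie below this mean for genes higher in the invasive fraction, without an effect of MK801. Matrix genes had a median of 1.07 in invasive versus core and 0.04 in MK801 versus core. Their difference from the mean does not by itself show such an effect. Matrix genes fell (34 of 35 lower, median -0.52, camera adjusted p = 2.7e-14, adjusted p = 0.308 with an estimated correlation), and so did mitosis genes (42 of 43 lower, median -0.57, camera adjusted p = 1.7e-15, adjusted p = 0.308 with an estimated correlation). Adjusted over the list alone, 10 matrix and 9 mitosis genes were past the threshold, all lower. Both lists passed in each of the 9 fits without 1 library, and after GC correction with medians of -0.67 and -0.43 (adjusted p = 0.258 and 0.531 with an estimated correlation). The matrix median was -0.33 without MK801 replicate 3, and neither list passed by fry (adjusted p = 0.079 for each), with which 2 of the 10 calls of this comparison stayed. After GC correction fry passed the matrix list (adjusted p = 0.049) and not the mitosis list (adjusted p = 0.301). DNA replication genes fell (35 of 40 lower, median -0.35, adjusted p = 0.44 with an estimated correlation) but not without MK801 replicate 3 (adjusted p = 0.208). Fibroblast and pericyte markers fell with the matrix genes (8 of 10 lower, median -0.48, adjusted p = 0.436 with an estimated correlation), a call lost without MK801 replicate 3 (adjusted p = 0.504) or invasive replicate 2 (adjusted p = 0.056). In all, 8 lists fell and 2 rose, the latter being ribosomal proteins (54 of 65 higher, median 0.32) and p53 targets (16 of 28 higher, median 0.15). Every one of the 10 calls was lost with an estimated correlation, with adjusted p = 0.308 or above. Of the 8 calls besides matrix and mitosis, 7 were lost without MK801 replicate 3 and that of ribosomal proteins without MK801 replicate 1 (median 0.04). Without MK801 replicate 3 the medians were -0.16 for DNA replication, -0.14 for fibroblast markers, -0.07 for axon guidance, -0.10 for the astrocyte-like and -0.28 for the oligodendrocyte-progenitor-like state, -0.24 for hypoxia, 0.39 for p53 targets and 0.54 for ribosomal proteins. Those of axon guidance, the astrocyte-like and oligodendrocyte-progenitor-like states, hypoxia and p53 targets were also lost without core replicate 1 or invasive replicate 2. Of these, axon guidance, hypoxia and p53 targets were lost without MK801 replicate 1 as well, and the oligodendrocyte-progenitor-like state without MK801 replicate 2. The adjusted p of these 5 lists was 0.051 to 0.127 in those fits and 0.191 to 0.414 without MK801 replicate 3. With the replicate number as a block, the calls of axon guidance and the oligodendrocyte-progenitor-like state were lost (adjusted p = 0.054 for each).

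The genes named as higher in MK801 than in the mean of the fractions were SLC12A8, LCP1, CALB2, MAGEH1 and CBX6, and those named as lower LAMB1, TM9SF2, COL7A1, FBN1, PBK and LOX. LAMB1, a laminin chain, was at 8.5 ± 1.76 FPKM in MK801, 13.8 ± 2.13 in core and 17.4 ± 0.774 in invasive libraries, and FBN1, which encodes fibrillin, at 4.25 ± 2.02, 10.2 ± 2.67 and 9.47 ± 1.18 FPKM in the same order. PBK, a mitotic kinase, was at 3.06 ± 1.68, 8.07 ± 2.01 and 7.36 ± 2.26 FPKM. PHLDA3, a p53 target, was at 59.3 ± 25, 25.3 ± 3.66 and 31.2 ± 7.16 FPKM. Limma called 0 genes, with 838 at an unadjusted p under 0.05, limma-voom called 0, and 0 genes were called in the same direction against both fractions. Without MK801 replicate 3, 447 genes were called in the comparison with the mean.

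Whether the genes that separate the fractions lie toward the invasive or the core side in MK801 libraries could not be resolved. Across genes, the invasive versus core difference and the difference of MK801 from the mean, 2 contrasts whose chance errors are uncorrelated only if all control libraries vary alike, correlated at r = 0.372. Simulated unchanged groups with the same libraries' spread gave -0.839 to 0.834 (median 0.082), and 59% of 100 draws were as large. The covariance was 0.0874, against a simulated mean of 0.0051. With the GC trend removed r was -0.04, and without MK801 replicate 1 it was -0.33. The 1068 genes called higher in the GC-corrected control libraries had a median difference of -0.01 between MK801 and the mean of the fractions. By library their mean level relative to all libraries was 0.38, -0.06 and -0.46 in MK801 replicates 1, 2 and 3, against 0.30 to 0.49 in invasive and -0.47 to -0.25 in core libraries.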

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

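The GC corrections, the covariate, the fits without the 2 libraries with the fewest genes detected (MK801 replicate 1 and invasive replicate 2) and the fits without libraries outside a comparison were chosen after the data were seen. So were, for the lists, leaving out 1 library and the groups compared alone. The other settings were planned. Causes of the changes below were not tested unless named. Pseudocounts, median-of-ratios scaling, no filter, robust empirical Bayes, a fold change above 1.2 and voom on recovered fragments called 0 genes in each of the 4 contrasts, as the reported fit did. Restricting to genes of at least 5 FPKM moved the median difference of all genes in invasive versus core from -0.02 to 0.24. For MK801 versus the mean of the fractions, fitting only the groups compared is the reported fit and gives no separate value. Depth ranged from 15.6 to 54.4 M fragments and limits low genes such as the glutamate receptors.

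In invasive versus core, 0 genes became 6 with quantile normalization, 6179 in the groups compared alone (the MK801 spread is then left out by construction), 7849 with library quality weights, 1 with protein-coding genes only, 2 with GC and length correction, 2037 with GC correction in the groups compared alone, 4 with genes detected as covariate, 14 without the 2 libraries with the fewest genes detected, and 689 with GC correction as well. Without 1 library the count was 0 to 4888, with 4675 without MK801 replicate 1, 1 without MK801 replicate 2 and 4888 without MK801 replicate 3. In MK801 versus core it was 8950 with quality weights and 0 to 5941 without 1 library, the highest without MK801 replicate 3. In MK801 versus invasive it was 1 with a filter of 5 FPKM, 28 with the replicate number as random effect, 5649 with quality weights, 74 with GC correction, 113 with GC and length correction, 43 with GC correction and block, 4 with GC correction in the groups compared alone, 323 with the covariate, 588 with GC correction without the 2 libraries, and 0 to 42 without 1 library, the highest without MK801 replicate 1. In MK801 versus the mean it was 8160 with quality weights, 55 with the covariate, 1 with GC correction without the 2 libraries, and 0 to 447 without 1 library, the highest without MK801 replicate 3. Quality weights gave 2699 genes in the same direction against both fractions, but those weights ran from 0.0717 to 1454, so that MK801 replicate 2 almost alone set its group's mean.

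The labels do not state that same-numbered libraries are paired, although the column names of same-numbered core and invasive libraries share a stem. The deviations of same-numbered libraries correlated at -0.150 to 0.608. Of the 9 libraries, 3 correlated best with their own number in both other groups. With the replicate number as block, 2525 genes were called in invasive versus core and 2399 with it as random effect, and 0 with the block in the other contrasts. Block and random effect also join MK801 libraries to control libraries of the same number, so neither isolates a pairing of core and invasive fractions. The block left 11 of 13, 2 of 2, 16 of 16 and 8 of 10 list calls in the order of contrasts above.

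The counts of lists called are over all lists tested and need not be the same lists. In invasive versus core, 13 became 4 with a filter of 5 FPKM, 7 with quantile normalization (4 higher and 3 lower), 0 with an estimated correlation before and after GC correction, and 3 by fry after GC correction. In the order of contrasts above, 7 of 13, 1 of 2, 8 of 16 and 2 of 10 calls were also past by fry. In MK801 versus core, 2 became 16 with no filter, 1 with a filter of 5 FPKM, 8 with GC correction (also with length, with block and in the groups compared alone), 9 without the 2 libraries, 11 with the covariate, 4 by fry and 0 with an estimated correlation before and after GC correction, and 2 to 9 without 1 library. In MK801 versus invasive, 16 became 10 without the 2 libraries, 9 by fry, 5 by fry after GC correction and 0 with an estimated correlation before and after GC correction. In MK801 versus the mean, 10 became 4 by fry, 5 by fry after GC correction, 0 with an estimated correlation before and after GC correction, and 4 to 14 without 1 library, 4 without invasive replicate 2 or MK801 replicate 3 and 5 without core replicate 1.

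Directions turned for the results that follow. The median of immediate-early genes in invasive versus core was -0.0314 with GC and length correction and -0.0292 with GC correction, also with block, with an estimated correlation, by fry and in the groups compared alone. The median of ribosomal proteins in MK801 versus invasive was -0.00555 to 0.465 without 1 library, and below 0 only without MK801 replicate 1, where the test still pointed up. The median of oxidative phosphorylation genes in MK801 versus invasive was -0.47 to 0.0407 without 1 library, and above 0 only without MK801 replicate 3. GRIN2D, not called in the reported fit, was -0.129 in invasive versus core with GC correction, with block and in the groups compared alone, -0.136 with length and -0.271 without the 2 libraries. For GRIN2D, MK801 versus core, it was -0.198 under the same corrections and -0.0371 without the 2 libraries. In MK801 versus invasive it was 0.0666 with quality weights, 0.234 with GC correction without the 2 libraries, and -0.521 to 0.109 without 1 library. In MK801 versus the mean it was -0.134 with GC correction and with block, and -0.130 with length. The correlation across genes of invasive versus core with MK801 versus the mean was -0.326 to 0.675 without 1 library, the lowest without MK801 replicate 1 and the highest without MK801 replicate 3.

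For the genes taken by the rule, 2694 of the values under alternatives kept their direction and side of the threshold, 538 came past the threshold in the same direction and 17 turned, all of GRIN2D. For the lists called, 848 kept both, 269 lost the call in the same direction and 8 turned.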

Other observations

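The tests of explanations below, GC content, library complexity and cells of another kind, were chosen after the results were seen. The counts over other splits of the libraries were planned. Glutamate handling genes did not pass as a list in any contrast of the reported fit (18 tested, 9 higher and 9 lower in invasive versus core, camera adjusted p = 0.473), although with the GC trend removed they passed in MK801 versus core (median 0.25, camera adjusted p = 0.022, adjusted p = 0.735 with an estimated correlation). GLUL, which makes glutamine from glutamate, was at 27.8 ± 3.16 FPKM in invasive and 16.4 ± 1.43 in core libraries (mean ± SD, 3 libraries), short of the threshold over all 9 libraries (limma adjusted p = 0.106). SLC1A5, a glutamine carrier, was at 85.1 ± 46.9 FPKM in MK801, 85.8 ± 38.1 in invasive and 35.4 ± 3.58 in core libraries. IER3, an immediate-early gene, was at 556 ± 221 FPKM in MK801, 361 ± 54.2 in invasive and 221 ± 27 in core libraries, while EGR2, another, was at 2.11 ± 0.929, 6.77 ± 1.71 and 4.24 ± 0.971 FPKM.

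IGFBP7, a mesenchymal-like state marker, was at 4.11 ± 1.04 FPKM in invasive, 1.66 ± 1.28 in MK801 and 0.190 ± 0.24 in core libraries. Of the markers of immune and endothelial cells, CSF1R was at 4.81 ± 0.884, 2.68 ± 1.71 and 1.98 ± 0.416 FPKM and TIE1 at 15.6 ± 7.16, 8.38 ± 3.28 and 6.34 ± 1.22 FPKM in the same order. Neither of these marker lists had the 5 tested members needed for a list test. These single genes cannot show that immune or endothelial cells were present.

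The broad difference between invasive and core libraries went with GC content, and a GC trend of the libraries is a candidate explanation of part of it. With the trend removed, 2037 of 11845 genes were called in the 6 control libraries, 1386 of them also called before with the same sign. This argues against the trend as the whole cause in that fit, although only 22.4% of the uncorrected calls stayed. With all 9 libraries the GC-corrected fit called 0 genes, as the uncorrected fit did. With the replicate block, GC correction took 2525 calls to 0. That block also ties MK801 libraries to control libraries of the same number. These 2 counts therefore cannot show what the GC trend does under a pairing of core and invasive fractions alone. Library complexity cannot be told apart from the fraction, since the lowest core library detected 1182 more genes than the highest invasive library. Whether MK801 replicate 1 resembles invasive libraries because it held more cells of the invasive kind stays open. Its matrix genes lay 0.797 (log2) below the lowest invasive library, but these were low in all MK801 libraries. The 1068 genes called higher and 969 called lower in the GC-corrected control libraries were at 0.38 and -0.45 in it, within the invasive ranges of 0.30 to 0.49 and -0.50 to -0.29. A difference in biology between the fractions stays open.

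Matrix genes were higher in invasive than in core and MK801 libraries. After GC correction at least 62.5% of the median difference remained in both comparisons, which argues against the GC trend as the whole cause. By fry, however, the matrix list in invasive versus core passed before GC correction (fry adjusted p = 0.017) and not after it (fry adjusted p = 0.05035). Every MK801 library lay at least 0.568 (log2) below every invasive library although their numbers of genes detected overlap, which argues against complexity for that comparison. Against the core, the median was 1.07 before and 0.787 after the number of genes detected was made a covariate (camera adjusted p = 8.0e-14), which took oxidative phosphorylation genes from 0.53 to 0.07. The numbers of genes detected do not overlap between core and invasive libraries, so the covariate rests on the spread within groups, widest among MK801 libraries. It cannot decide whether complexity underlies the difference from the core. Fibroblasts could bring collagen. COL3A1, DCN and LUM are abundant in fibroblasts and were chosen after their values were seen. They were higher in mean FPKM by a median of 0.293% of the difference in COL1A1. This argues against fibroblasts rich in these 3 genes as the main source of the COL1A1 difference. It does not exclude other cells, since the fibroblast and pericyte list rose. COL3A1 itself rose from 0.413 ± 0.172 FPKM in core to 2.72 ± 1.09 in invasive libraries. A matrix programme of the invading tumour cells that MK801 libraries lack is a hypothesis open beside the unequal share of invasive cells in the pools, which was not measured. Sequencing the invasive fraction of MK801 devices apart from their core, with the share of invasive cells counted, would decide between them.

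Mitosis genes were lower in MK801 libraries. Against the core, the median went from -0.53 to -0.0963 after GC correction, so the GC trend may account for that difference. Against the invasive fraction it was -0.710 after correction. Before correction every invasive library lay at least 0.424 above every MK801 library. After it the lowest invasive library was at 0.319, and MK801 replicates 1, 2 and 3 at 0.141, -0.325 and -0.606. These MK801 levels fell as the genes detected rose (15161, 19031 and 21517). The groups still did not overlap, which argues against the GC trend and complexity as the whole cause there. Whether fewer dividing cells in MK801 devices or the makeup of the pools underlies this stays open.

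Other splits of the libraries were counted for each result, the real split included. The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05. Where the real split gave 0 genes, every split gives at least as many, 10 of 10 or 100 of 100, and the count says nothing about chance. This holds for invasive versus core (highest other 0), MK801 versus core (highest other 2), MK801 versus invasive (highest other 1), MK801 versus the mean (highest other 4414, which points to a structure of the samples other than the groups) and genes in the same direction against both fractions (highest other 1). Only the real split, 1 of 10, gave the 13 lists of invasive versus core (highest other 12), the 16 of MK801 versus invasive (highest other 11), the 6179 genes in the 6 control libraries (highest other 2), the 2037 after GC correction (highest other 1) and the 74 of MK801 versus invasive after GC correction (highest other 0). In MK801 versus core all 10 splits gave at least 2 lists (highest other 13). Camera at the preset correlation of 0.01 thus also called lists under groupings other than the real one, which limits the weight of the list calls. What underlies those calls was not tested. Of 100 drawn splits of the 9 libraries, 27 gave at least the 10 lists of MK801 versus the mean (highest other 15), so chance cannot be excluded.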
